A study of Caenorhabditis elegans with 4 samples.

How the data were processed

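Chromatin immunoprecipitation followed by sequencing was carried out on L3 hermaphrodites of strain OP18 with an antibody against EGFP. Per the labels, 4 libraries were made, a ChIP and an input library in each of 2 replicates. The labels do not say how far back the replicates were separate. Samples were grouped as ChIP or input from their descriptions. The values used are q-values per region in the authors' deposited list, which names PeakSeq as its source and WormBase WS180 as its genome build, per the file headers and columns. One list covers both replicates, and how they were combined is not given in the sources used here, nor are the aligner, the versions, the read filters or the q limit. The largest q is 0.00999, just under 0.01. A q-value ranks regions within this list and depends on width and depth as well as on enrichment. No value belongs to a single library, so no spread between replicates, no test between replicates and no leave-one-out was computed.

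The way q was formed was worked out from the values, a step chosen after the data were examined. The list is in order of q multiplied by place in the list, which never falls, whereas q itself falls at 3650 steps. This is the form of a Benjamini-Hochberg value, p multiplied by the number of tests and divided by rank, without the step that makes it monotone. The number of tests N was searched up to 150000. At N = 25497 all 60 of the most common values equalled a binomial tail with probability 0.5, while the next best N matched 1. Each p was then solved for a pair of whole numbers, k for ChIP and m for input, such that p is the probability of at most m successes in k + m trials. The relative tolerance on p was 3e-11 (wider for the 2 regions with numbers beyond the search table). A single pair was found for 7483 regions (99.9%), 10 regions had 2 possible pairs and were left out of values that need reads, and no region had none. With N raised or lowered by 1, 0 of the 7493 regions matched. Defining the tail with a strict inequality moves 1 read between k and m and fits equally well; that form was run as an alternative. The reads are therefore inferred under this binomial form and were not listed by the authors.

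The ChIP numbers take all values, whereas the input numbers skip some. For each chromosome the factor whose multiples, rounded up, best covered the input numbers was found in steps of 0.0005. It covered 95.6 to 98.5% of the regions, where chance gives 50.4 to 72.2%. Over all regions rounding up covered 97.1%, rounding down 84.5% and rounding to the nearest 75.3%. Input before scaling is the scaled number divided by this factor and rounded down. Enrichment is k divided by m. Input per kb is the input before scaling over the region width plus 200 bp, and relative input divides it by the median over the listed regions of the same chromosome. Both describe listed regions only, which were selected for high ChIP over input, so a listed region with low enrichment needs many reads. Listed regions held 871675 ChIP reads, 204051 input reads before scaling and 367111 after. To recompute calls, the input of chromosome I was multiplied by another factor and p was recomputed. Reads were available for 1776 of its 1784 regions, and regions with 2 possible pairs kept their deposited p. Regions were kept up to the last rank with q at or below 0.01 for the same N. A region that was tested but not listed cannot enter this way, because the limit on p only falls.

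Chromosome spans run from 1 to the largest region end. Densities are regions per Mb of span, and the exact (Clopper-Pearson) 95% binomial interval of a share was turned into that of a density ratio. These intervals and Fisher's exact test cover counting error only and treat regions as independent, which clustered regions are not. Arms are the outer 30% at each end. Spacing was compared with 1000 sets of midpoints placed uniformly on each chromosome, with two-sided permutation p-values whose smallest value is 0.0020. Coordinates are 1-based on WS180. Named regions are, by a rule fixed before the data were examined, those among the 25 with the smallest q; regions named for width, enrichment with at least 200 reads, groups, windows, gaps and the stretch on chromosome III were chosen after their values were seen. The rule also names genes where an annotation of the same build can be used; the gene table at hand is for assembly WBcel235, so no gene was assigned to a region. Promoter share, coverage of gene lists, scores by location, the Hox motif and k-mers needed the WS180 genome or annotation and were not analysed here.

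The procedure was tested on a simulated list of 8193 regions from 20000 tests. It returned the number of tests and all factors, a single pair for 99.9% of the regions, and the simulated pair in 100% of those. The simulated list was built with the same binomial form, rounding up and ranking that the procedure assumes. It therefore checks the calculation and not whether the deposited list follows that form. In a simulated list of 6000 regions without differences the ratio for chromosome I was 1.03 and the spacing p 0.468 (permutation test, 200 sets). With a built-in excess of 1.5 on chromosome I and paired regions, the ratio came out at 1.495 and the spacing p at 0.00995 (permutation test), the smallest that 200 sets can give. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Alternatives covered the better-scoring 50% of regions, merging, covered length, arm size, distance and way of placing, chromosomes left out, the scaling of chromosome I, the form of the binomial tail and the length added to widths.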

Results

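The data describe where LIN-39, a Hox homeodomain transcription factor of the central body region, was found on the genome of Caenorhabditis elegans larvae at the third larval stage (L3). LIN-39 is known for its part in specifying vulval precursor cells, in the fates of ventral cord neurons and in the migration of neuroblasts. Hermaphrodites of strain OP18, which carry a LIN-39::EGFP transgene together with a wild-type copy of unc-119 in an unc-119 mutant background, were grown at 20 °C and crosslinked with 2% formaldehyde. Chromatin bound by the fusion protein was precipitated with a goat antibody against EGFP and sequenced (ChIP), and DNA that had not been precipitated was sequenced alongside (input). There were 4 libraries, 2 of ChIP and 2 of input. The authors' deposited list combines the replicates, so every value below belongs to the combined comparison of ChIP with input and has no spread between replicates. Read totals of the libraries were not used here, and depth is given as the reads within each region.

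The comparison asks which parts of the genome were enriched in the ChIP libraries over input. In the authors' deposited list 7493 regions on 6 chromosomes passed, all with q below 0.01. They covered 3580 kb, or 3.58% of the 100.1 Mb between the chromosome starts and the last region ends, at 74.9 regions per Mb. The median width was 364 bp with an interquartile range of 249 to 562 bp. At the extremes, 303 regions were narrower than 50 bp and 18 were at least 4000 bp wide. Reads were inferred from the q-values under a binomial form, which gave 25497 tested regions and a ChIP and scaled input number for 7483 of the 7493 listed ones. The median region held 81 ChIP reads against 32 scaled input reads. The median enrichment was 2.60-fold, with an interquartile range of 2.09 to 3.41. Enrichment was at least 2-fold in 80.1% of these regions, at least 3-fold in 36.2% and at least 5-fold in 7.46%. These ratios belong to the combined list and carry no interval, because the input number was scaled before the test.

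**Figure D1:**
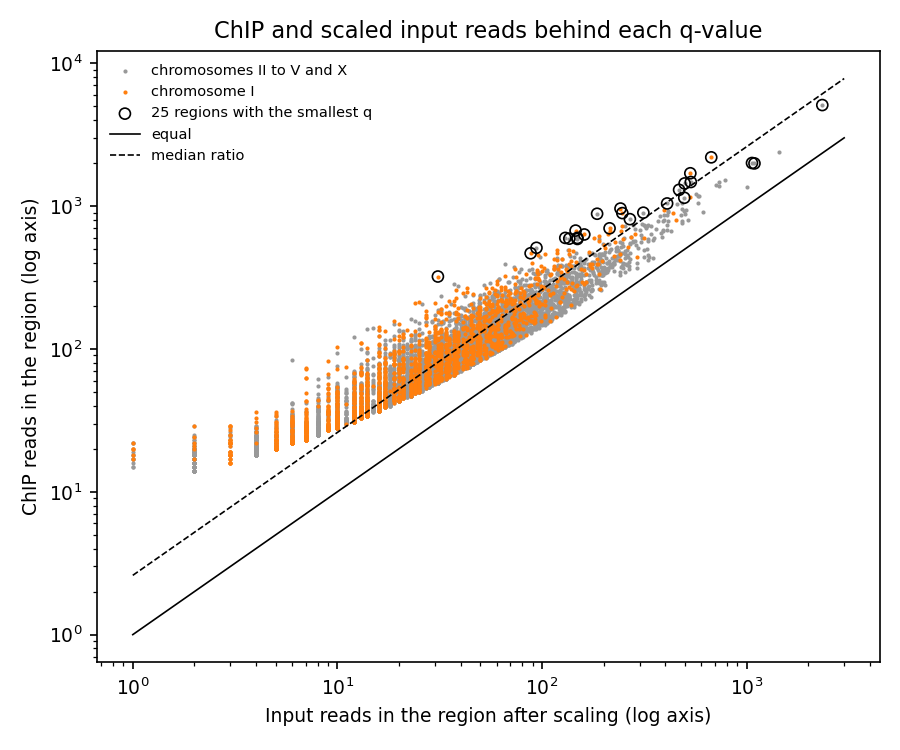
ChIP reads (vertical, log axis) against scaled input reads (horizontal, log axis) for 7483 regions, with chromosome I in orange and the 25 regions with the smallest q circled. Every point lies above the solid line of equal numbers, and the dashed line marks the median ratio of 2.60.

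The smallest q belonged to a 7810 bp region on chromosome III, from 7529752 to 7537561 in WS180 coordinates, at q = 3.83e-223 in the authors' deposited list, with 5088 ChIP reads against 2345 scaled input reads. Its enrichment was 2.17-fold, below the median of the list, and its input per kb was 4.70 times the chromosome's median region. The second region, on chromosome I from 1834867 to 1837883, was enriched 3.26-fold with 2191 ChIP reads and q = 1.59e-182, and its input per kb was 4.62 times the median of its chromosome. Another region on chromosome I, from 9379878 to 9384206, followed at 3.19-fold (1695 ChIP reads, q = 2.63e-137). The region on chromosome V from 4506715 to 4508610 was enriched 4.75-fold (883 ChIP reads, q = 1.51e-105), and that on chromosome III from 1923079 to 1927028 was enriched 2.89-fold (1439 ChIP reads, q = 4.11e-102).

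Among the 25 regions with the smallest q, 9 lay on chromosome I, 4 each on V and X, 3 each on II and III, and 2 on IV. They were wide, with a median of 2444 bp against 364 bp in the later regions. Their median enrichment by the deposited scaling was 3.26-fold against 2.60-fold. The ratios ranged from 1.82-fold, in the 7312 bp region on X from 6738525 to 6745836, to 10.4-fold, in the 536 bp region on I from 435418 to 435953, which held 321 ChIP reads against 31 scaled input reads. On chromosome II the region from 8328544 to 8329343 was enriched 5.43-fold, and on IV the region from 14032400 to 14035051 was enriched 2.77-fold. On X the leading region, from 16929326 to 16932035, was enriched 2.76-fold with 1472 ChIP reads.

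Rank by q and rank by enrichment were different orders. The 18 regions of at least 4000 bp had a median enrichment of 1.97-fold by the deposited scaling. None exceeded 3.19-fold, the ratio of a region on chromosome I. The widest of all, on chromosome II from 10541815 to 10552898, held 2391 ChIP reads against 1437 scaled input reads, a ratio of 1.66. At the other end, 126 regions were enriched at least 8-fold, but their median width was 33 bp and their median scaled input was 2 reads, so these ratios rest on few reads. Among the 972 regions with at least 200 ChIP reads the median was 2.31-fold. By the deposited scaling, high ratios among them were found on I from 435418 to 435953 (10.4-fold), on I from 961235 to 961669 (8.79-fold, 211 ChIP reads), on I from 14346539 to 14347032 (8.56-fold, 214 reads) and on IV from 1906708 to 1907288 (7.96-fold, 207 reads). With the input of chromosome I scaled by the mean factor of the other chromosomes, the ratios of these regions on I were 7.64, 6.39 and 6.11, below that of the region on IV. Regions on IV from 12771306 to 12771939 (7.70-fold), on X from 4802315 to 4802786 (7.28-fold) and on II from 6707448 to 6708013 (7.03-fold) then also exceeded the latter pair on I.

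Regions were unevenly spread over the chromosomes. Chromosome I held 1784 regions, 23.8% of the list (exact 95% binomial interval 22.8 to 24.8) on 15.02% of the span, or 118.7 per Mb. The next densest was X, with 1509 regions at 85.4 per Mb, followed by III (1068, 77.6 per Mb), II (1057, 69.2 per Mb), IV (1055, 60.4 per Mb) and V (1020, 48.8 per Mb). The density on chromosome I was 1.77 times that of the other chromosomes together (1.68 to 1.87), and that on X was 1.18 times that of the autosomes (1.11 to 1.24). On V the ratio to the other chromosomes was 0.598 (0.559 to 0.639). The intervals cover counting error within this list only. Among the regions with the smallest q the ratio for chromosome I was 3.18 (1.24 to 7.65) for the first 25, 4.18 (3.12 to 5.58) for the first 200 and 2.47 (2.15 to 2.83) for the first 1000. With the input of chromosome I scaled by the mean factor of the others, these ratios were 1.79 (0.584 to 4.65), 1.55 (1.08 to 2.18) and 1.38 (1.17 to 1.61), and 6 of the first 25 regions lay on I. All 15 complete 1 Mb windows of chromosome I held more regions than the median window of the other chromosomes, with 76 to 166 regions against a median of 70.5.

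**Figure D2:**
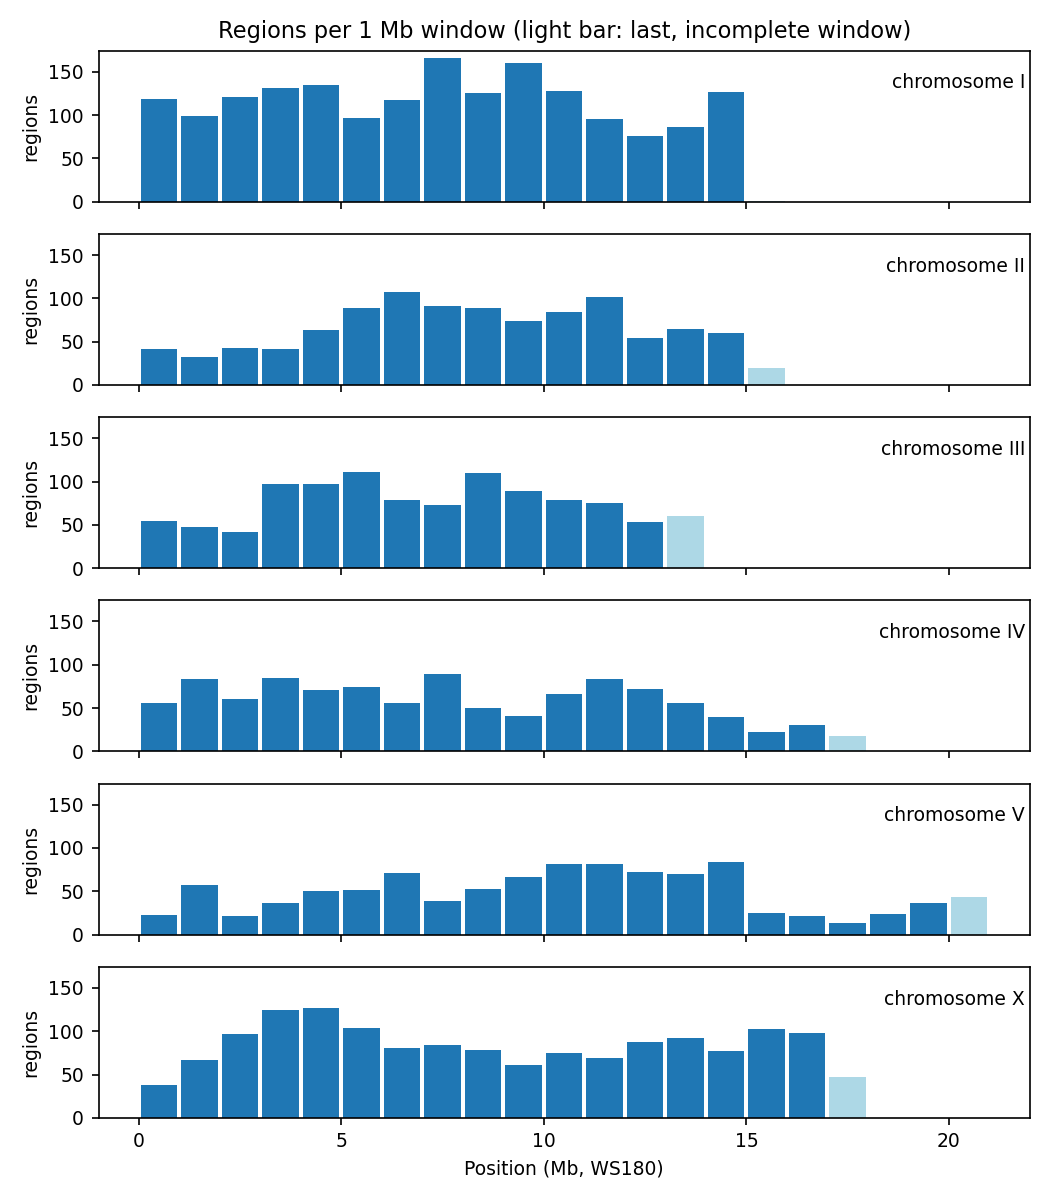
Number of regions (vertical) in 1 Mb windows along each chromosome (horizontal, Mb). The 15 complete windows of chromosome I hold 76 to 166 regions, against a median of 70.5 in the complete windows of the other chromosomes.

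The scaling of the input also set chromosome I apart. The scaled input numbers skip values at regular intervals, which gives the factor by which input reads were multiplied on each chromosome. The factor was 1.39 on chromosome I and 1.81 to 1.98 on the others, with a mean of 1.897. Before scaling, ChIP reads in the listed regions were 3.93 times the input reads on I and 4.28 to 4.52 times on the others. After scaling, the ratio of sums was 2.80 on I and 2.24 to 2.35 elsewhere, and the median enrichment was 3.00-fold on I against 2.50-fold elsewhere. With the input of chromosome I multiplied by 1.897 instead, 1127 of its 1784 regions remained below q = 0.01, at 74.96 per Mb, and the density ratio to the other chromosomes was 1.14 (1.07 to 1.21). By this factor chromosome I (interval 71.0 to 79.1) was less dense than X (83.6 per Mb, 79.8 to 87.4). These intervals treat clustered regions as independent, and the order of I and X was not examined with other factors. Its interval overlapped that of III (76.6 per Mb, 72.4 to 81.0), so the order of I and III was not resolved. With the lowest and highest factor of the others the density ratio of I was 1.22 and 1.07. By the mean factor, the median enrichment on chromosome I was 2.19-fold over all its listed regions, and 2.48-fold over the 1127 that passed the q limit again. The complete 1 Mb windows of I then held 50 to 110 regions, and 9 of the 15 lay above the median of 68 in the other chromosomes. The whole list fell from 7493 to 6732 regions.

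**Figure D3:**
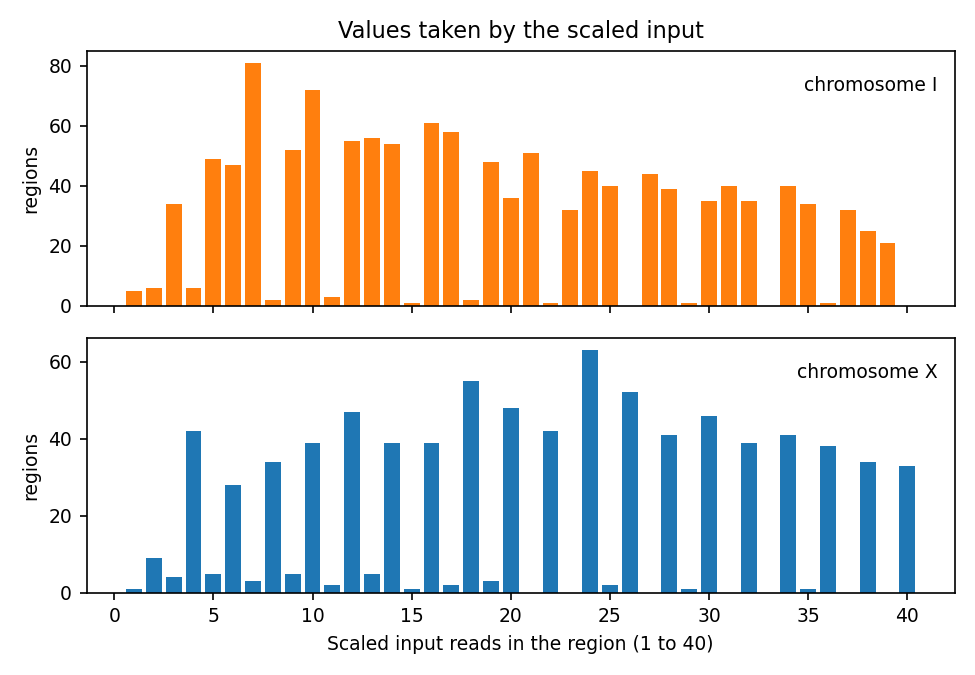
Number of regions (vertical) at each scaled input number from 1 to 40 (horizontal) on chromosomes I and X. Of the 40 values, 21 hold fewer than 10 regions on X, where the factor is 1.98, and 13 on I, where it is 1.39.

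**Figure D4:**
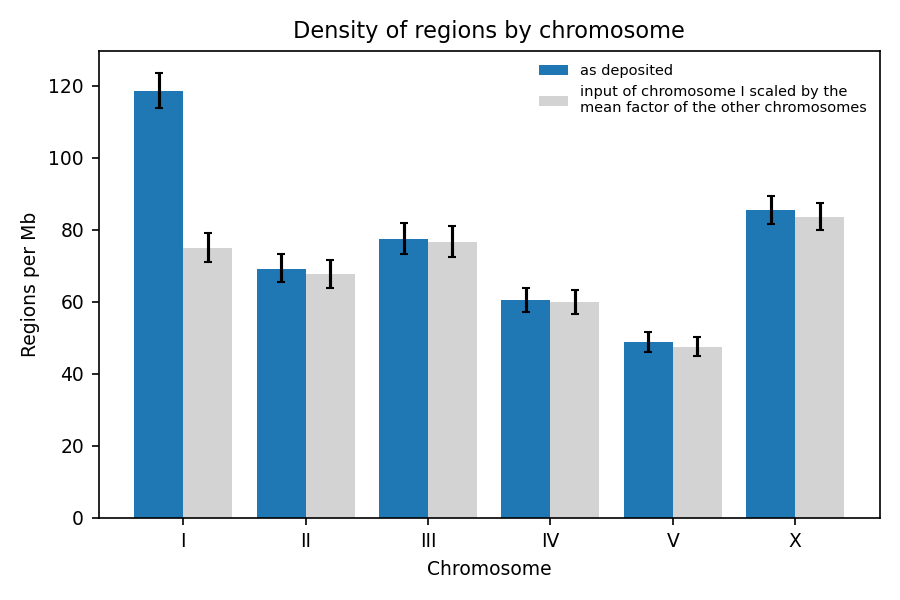
Regions per Mb (vertical) on each chromosome as deposited and with the input of chromosome I scaled by the mean factor of the others. Bars carry exact 95% binomial intervals, and chromosome I moves from 118.7 to 74.96 per Mb.

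Chromosome arms and centres differ in gene content in this species, and regions were less dense in arms than in centres on the 6 chromosomes together. Taking the outer 30% at each end as arms, 4102 regions lay in arms and 3391 in centres, so the density in arms was 0.806 times that in centres (exact 95% binomial interval 0.770 to 0.844). The ratio was lowest on V, at 0.528 (0.466 to 0.599), followed by II at 0.670 (0.593 to 0.758), III at 0.752 (0.665 to 0.849) and I at 0.824 (0.750 to 0.905). On IV the interval included 1 (0.896, 0.792 to 1.01), and its arms differed. The left arm of IV was denser than its centre (72.7 against 64.4 per Mb), and the right arm was less dense (42.7 per Mb). The X chromosome went the other way, with 964 regions in arms and 545 in the centre, a ratio of 1.18 (1.06 to 1.31), whereas the autosomes together had 0.735 (0.698 to 0.774). The odds of lying in an arm were 1.60 times higher on X than on the autosomes (Fisher's exact test over regions, two-sided, p = 1.19e-15, which treats regions as independent). With arms of 25% the ratio on X was 1.01 (0.909 to 1.12), and with regions whose midpoints lay within 2000 bp counted once it was 1.105 (0.981 to 1.25), whereas arms of 35% gave 1.21 (1.08 to 1.36) and the better-scoring 50% of regions gave 1.201 (1.03 to 1.398). The longest stretches without a region were on V, from 17139294 to 17697961 (559 kb) and from 2255494 to 2600587 (345 kb).

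Regions lay closer together than random placing would put them. The nearest neighbouring midpoint was within 2000 bp for 3022 regions, or 40.3%, against a mean of 27.4% (25.3 to 29.5%) in 1000 sets of the same number of midpoints placed uniformly on each chromosome, a ratio of 1.47 (permutation test, two-sided, p = 0.0020, the smallest these sets can give). Within 1000 bp the observed share was 12.3% and the ratio was 0.825 (permutation p = 0.0020), in a list where no gap between regions was under 200 bp. When the placed regions kept their widths and such gaps, the ratio was 2.01 at 1000 bp and 1.99 at 2000 bp (permutation p = 0.0020 for each). Groups of at least 5 regions with neighbouring midpoints within 2000 bp numbered 50. The largest held 12 regions over 10.5 kb on chromosome I, from 7361813 to 7372280, and the next held 10 regions on I from 6275635 to 6288042. Outside chromosome I, the leading group held 8 regions on IV from 11347106 to 11354923. Counted in 997 windows of 100 kb over all chromosomes, the variance was 3.26 times the mean, and 30 windows had no region. This variance includes differences in density between chromosomes, which were not separated out. The fullest window, on I from 7300001 to 7400000, held 28. These groups and 100 kb windows were counted by the deposited scaling only. Rescaling the input of chromosome I by the mean factor of the others removed 657 of its 1784 regions.

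The neighbours of the first-listed region on chromosome III shared its high input. From 7523950 to 7554200, a stretch of 30.3 kb, all 7 regions had input per kb between 1.98 and 5.68 times the chromosome's median region, with a median of 4.51. Their enrichment was low, from 1.349-fold to 2.27-fold. The most enriched of them, from 7548755 to 7549506, held 724 ChIP reads against 319 scaled input reads. The next region to the right, from 7559854 to 7560180, had input per kb at 0.857 of the median and was enriched 2.90-fold, and the next to the left, from 7503216 to 7503464, had 0.603 and 2.88-fold. Farther out, the region from 7570186 to 7570783 again had high input per kb, at 2.56, with an enrichment of 1.52-fold, and that from 7499487 to 7499801 had 1.52 and 1.898-fold. The stretch was chosen for its input after the values had been seen. It is the unbroken run of listed regions around the first-listed one with relative input of at least 1.5. That all its regions were high and that the next ones lay below 1.5 follows from this rule. Low enrichment beside high input also follows in part from selection, because a listed region with low enrichment needs many reads. Of all listed regions with inferred reads, 23.9% reached 1.5.

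**Figure D5:**
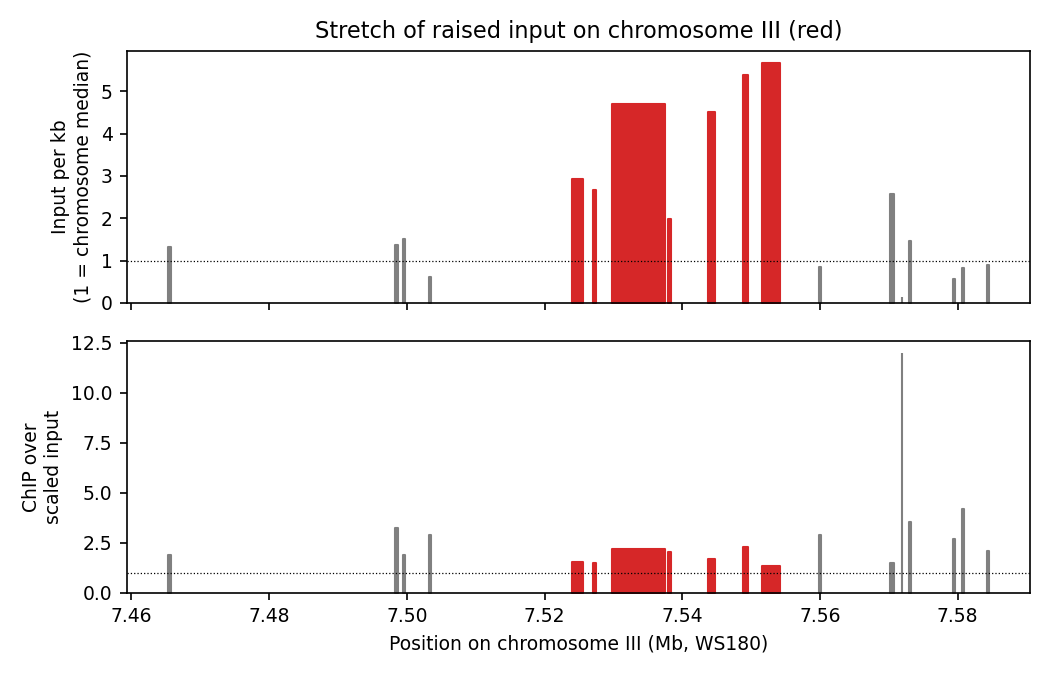
Input per kb relative to the chromosome's median region (top) and ChIP over scaled input (bottom) for regions around the stretch, drawn at their positions on chromosome III (Mb). The 7 regions in red lie at 1.98 to 5.68 in input and 1.349 to 2.27 in enrichment.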

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

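The alternatives with rescaled input, left-out chromosomes, other ways of placing, joined regions, the tail form and the length added to widths, and all those for median enrichment, chromosome I density and X arms, were chosen after seeing the data. No paired analysis was possible because the replicates share 1 combined list with no value per library, and leaving out each replicate could not be done for the same reason. Alternatives that need the WS180 genome or annotation (promoter share, gene list coverage, score by location, Hox motif and k-mers) were not run. Merging regions that overlap or touch left 7493. The better-scoring 50% holds 3747 by construction. Density on X stayed above that of autosomes, at 1.196 to 1.31, the highest being 1.31 with rescaled input on chromosome I. The density ratio of chromosome I stayed above 1 but moved in most alternatives, from 1.77 to 1.89 in the better-scoring 50%, 2.70 in the first 10%, 3.18, 4.18 and 2.47 in the first 25, 200 and 1000, 1.53 by covered length and 1.53 with near regions counted once. It fell to 1.14, 1.22 and 1.07 with its input scaled by the mean, lowest and highest factor of the others; the cause is the alternative itself, since only the factor changed. With the mean factor it was 1.46 in the first 10% and 1.79 (interval 0.584 to 4.65), 1.55 and 1.38 in the first 25, 200 and 1000. The counts by the mean, lowest and highest factor were 6732, 6822 and 6661. Arms stayed below centres in all 10 alternatives, moving to 0.736 and 0.846 for arms of 25% and 35%, 0.755 in the better-scoring 50%, 0.863 without V and 0.735 without X. On X alone the ratio of 1.18 became 1.01 with arms of 25%, the cause was not tested, and 1.105 to 1.21 in the other 3 alternatives. Spacing stayed above random in 7 of 8 alternatives, from 1.18 to 2.01, and reversed to 0.825 within 1000 bp under uniform placing, which lets regions overlap; with widths and gaps kept it was 2.01. Median enrichment ranged from 2.46 to 2.80 and input in the stretch on III from 3.11 to 5.17. Depth limits the ratios of the 126 regions enriched at least 8-fold, whose median scaled input was 2 reads.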

Other observations

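All tests in this part were chosen only after the data had been seen, those on clustering before their own results.

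The excess of regions on chromosome I was weighed first. An excess of regions near the q limit only is argued against, since the density ratio was 2.70 among the first 10% of regions, and 1.46 (1.202 to 1.76) with rescaled input. A few crowded stretches are argued against for the deposited list, since 100% of the complete 1 Mb windows of chromosome I lay above the median window of the others, but not for what remains after rescaling, where 60% did. Whether a lower scaling of the input on chromosome I accounts for the excess in the whole list was not decided. The ratio over all regions depended on the factor and fell to 1.14 with the mean factor of the other chromosomes. However, a higher factor can only remove regions, so the direction of this fall was fixed beforehand. The bound of 1.2 was set after the counts were known, and the lowest factor gave 1.22. Multiplying any other chromosome's factor by the same 1.37 removed 44.6 to 48.4% of its regions against 36.8% on I, so such a loss is not particular to I. With the mean factor a ratio above 1 remained at small q, at 1.46 in the first 10% of regions. Ratios at small q were not computed with the other factors, so whether scaling accounts for that remainder was not decided. Whether the lower factor followed a true difference in background between the libraries stays open, and no biological explanation was tested.

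The raised input around the first-listed region on chromosome III was weighed next. A general rise of input around strongly bound regions was not decided. The neighbours of the other 24 regions among the 25 with the smallest q had a median relative input of 1.22, the highest being 2.47. For 0 of these 24 did the neighbours reach the 3.72 found around the first-listed region. That bar was set by a stretch noticed for its input, so this count decides nothing, and how unusual the stretch is cannot be told. A small q also does not mark strong enrichment, since ratios among the 25 went down to 1.82-fold. Extra copies of one contiguous stretch in the genome of the strain were not decided either: 0% of 3276 regions elsewhere with at least 5 neighbours within 20 kb had neighbours as high, with the same limit. A first form of the test has the same limit and gave 2.92 as the highest median among 7444 other runs of 7 neighbouring regions, against 4.51 in the stretch. The strain carries an integrated lin-39 transgene and lin-39 lies on chromosome III, so extra copies stay open as a hypothesis. A general rise around strongly bound regions, sequence repeated elsewhere and any other local rise of input stay open too. The WS180 position of lin-39 was not used here.

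The clustering of regions was weighed last. Differences in density between megabase windows are argued against as the whole cause, since placing midpoints within their own 1 Mb window left a ratio of 1.397 (40.3% against 28.9%). Splitting of wide bound stretches into pieces at most 500 bp apart is argued against as the whole cause. Joining regions with gaps of up to 500 bp left a ratio of 1.18 (30.2% against 25.6%, with 28.8% the highest of the placed sets). Splitting into pieces farther apart was not tested. The joined regions were compared with uniform placing on each chromosome, not with placing within 1 Mb windows. Joining removes close neighbours by construction, so the fall from 1.47 to 1.18 does not measure how much splitting contributes. Uneven gene density below 1 Mb and regions that reads cannot be placed in were not tested, and no biological explanation was tested.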
